A study of Mus musculus with 24 samples.

How the data were processed

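RNA from hearts of C57BL/6 mice was hybridised to 24 spotted 2-colour arrays. Per the labels' protocols, anesthetized mice had 40 min of coronary occlusion and 60 min of reperfusion (IR). The conditioning groups had 3 cycles of 1 min of ischemia and 1 min of reperfusion, which came 10 min before ischemia (PreC), 1 min after the start of reperfusion (PostC) or 30 min after it (Post30). A further set of arrays held RNA of the non-ischemic region of IR hearts (NonIschemic). RNA of the ischemic region of IR hearts was the other channel of every array. Per the labels' protocols, total RNA was amplified, and the RNA of a condition was divided between Cy3 and Cy5.

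The deposited array files hold, per the file headers, foreground and local background intensities of 2 channels and a quality mark for each of 17664 spots. Their image analysis software is not given in the sources used here. The deposited value table holds the authors' processed log2 ratios. Set against the array files, its values were the log2 ratio of channel 1 over channel 2 without background subtraction, with the intensity trend removed. Within intensity bins of the brightest spots its slope on that ratio was 0.991 to 1.00. Column medians lay between -0.013 and 0.0083. Its normalization method and software stay unknown, and its sign was turned before use. The background-corrected ratios tested here then correlated with it with r from 0.361 to 0.764 per array.

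Mouse probes took 16655 spots and made 16463 probes, of which 12 were printed on 17 spots each and averaged. Control and empty spots (1009) were left out of the tests and had weight 0 in loess. Between 2 and 25 spots per array carried a quality mark and were left out. If a spot was marked in either dye orientation, the extract pair had no value for that probe. The files do not pair the probe IDs with genes, and 0 of the IDs were found in the gene table for assembly GRCm38.p6. No gene could therefore be named, the 25 gene lists fixed before the data were examined were not tested, and at most 2 probe IDs that rose and 2 that fell are printed. They are those with the largest change in the comparison of any conditioning with IR, among probes with an adjusted p under 0.05 and the same sign in all 9 extract pairs.

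Background was corrected with normexp, and each array was normalized by global loess, with limma 3.58.1 in R 4.3.3. The plan was an offset of 50, which is meant for scanners that reach 65535. Intensities here reached only 1356, with array medians of 1.29 to 4.26, so the offset was scaled by the same ratio to 1.03. The literal offset of 50 was run as an alternative. The scaled offset was thus chosen after the intensity range was seen, before any test was counted, and the offset of 50 is the setting fixed beforehand.

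The log2 ratio is channel 2 (the group's RNA) over channel 1 (IR RNA). The file channels followed the RNA and not the dye: the control probes 1RC and 3RC were negative and 2RC and 4RC positive on 24 of 24 arrays, in both dye orientations. The channel with the higher background was that of Cy3 on 24 of 24 arrays if file channel 1 is the IR channel of the labels. The direction is therefore likely and not settled, since a reversed channel numbering in every file would turn every sign. Same-orientation arrays of different groups correlated with r from -0.0007 to 0.578.

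Both dye orientations of a group and replicate number were averaged as 1 replicate, which gave 12 extract pairs and n = 3 per group. Ratios of the 2 orientations of a pair correlated with r from 0.0387 to 0.461. Deviations of the 2 orientations of a pair from their group means correlated with r from 0.156 to 0.395, higher than with any other number of the group in 12 of 12 pairs. The labels do not say whether replicate numbers stand for separate hearts or pools. The p-values then measure only the spread between these samples, which may be technical. The ratio was tested against 0, which leaves out the spread of the IR hearts except as far as the numbers hold different IR RNA.

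Group means of all 12 pairs were fitted with limma (lmFit and eBayes), with 8 residual degrees of freedom. Benjamini-Hochberg adjustment was made over all probes in each of 8 comparisons, at 0.05. Deviations of same-numbered samples correlated with r from 0.215 to 0.396 in 9 of 9 pairs of conditioning groups, so the numbers, taken from the labels, pair these groups. With NonIschemic they reached 0.1 in 6 of 9 pairs (0.0102 to 0.378). The values were 0.161 to 0.378 in numbers 1 and 2 and 0.0102 to 0.0774 in number 3. The numbers therefore pair NonIschemic only in part. A fixed block takes the shared deviation out of the residual and leaves it in the group means, which makes p-values against IR too small.

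The fits were tested on simulated data with the spreads of 16309 probes, 200 of them changed, in 10 simulations. With a correlation of 0.25 within a replicate number, the comparison of postconditioning with IR recovered 44.2% of log2 changes of 0.25 and 97.8% of changes of 0.5, with 5.88% false calls. The comparison of any conditioning with IR had 24.5% false calls in the fit of group means, 50.4% with a fixed replicate block and 8.64% with the replicate number as a random block. Without that correlation the fit of group means had 5.79% false calls. The value of 0.25 is near the correlation of residuals of same-numbered pairs over all probes, which was 0.245 with the pairs of NonIschemic included. Between conditioning groups alone the pairs had 0.215 to 0.396, so 0.25 may be too low for the comparison of any conditioning with IR. The consensus correlation that limma estimated for the random block was lower, at 0.0782. Simulated with that value, the comparison of any conditioning with IR had 9.04% false calls in the fit of group means, 12.7% with the fixed block and 7.27% with the random block. The estimate ran low in simulated data, with a mean of 0.0314 where the correlation was 0.0782 and 0.185 where it was 0.25.

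The alternatives fixed beforehand changed the background correction, the normalization, the source of values, filters, dye-swap handling, samples in the fit, array weights, pairing, thresholds and single replicates. The random block, a scaling to control probes and the fits without replicate number 2 were added after seeing the data. Detection was set at the 95th percentile of 481 empty spots. Between 29.8% and 49.8% of mouse spots passed it per channel, and the number of arrays limits the precision.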

Results

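Gene expression was measured in mouse hearts after 40 min of ischemia and 60 min of reperfusion (IR), with or without conditioning, which is a series of short occlusions around the long one. Each of 4 groups had 6 arrays, which were 3 replicate numbers in 2 dye orientations. The groups were hearts with cycles before ischemia (PreC), 1 min into reperfusion (PostC) or 30 min into it (Post30), and the non-ischemic region of IR hearts. On average 37.8% of mouse probe spots were detected above empty spots in the group's channel and 43.2% in the IR channel. All ratios are group over IR RNA, in a direction that is likely and not settled, and the files do not pair the probes with gene names.

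The comparison of the ischemic with the non-ischemic region of IR hearts asked what differed between the regions after occlusion. The groups hold no heart without occlusion, so its effect cannot be told apart from standing differences between the regions. With limma and Benjamini-Hochberg adjustment, 0 of 16463 probes passed (smallest adjusted p = 0.0825). At an unadjusted p under 0.05 there were 2051, or 12.5%, against the 5% that chance gives on average. Of these 2051, 1089 were higher and 962 lower in the ischemic region. How far such a share strays from 5% without any effect was not computed, here or in the comparisons below. Under median centring 40 probes passed, 40 higher and 0 lower. Without NonIschemic replicate 2 the count at an unadjusted p under 0.05 was 1010, or 6.13%. With the replicate number as a fixed block, 386 probes passed, a fit whose p-values against IR are too small.

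Preconditioning was compared with IR to find transcripts that differ when the cycles come first. With limma, 0 of 16459 probes passed (smallest adjusted p = 0.401), and 1126, or 6.84%, had an unadjusted p under 0.05. Without PreC replicate 1 that count was 624, or 3.79%, below the 5% that chance gives on average. The fixed replicate block gave 40 probes.

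Postconditioning gave 0 probes past the threshold of 0.05 with limma, with a smallest adjusted p of 0.0537. At an unadjusted p under 0.05 there were 2233 probes, or 13.6%, of which 960 were higher and 1273 lower than in IR. At an adjusted p under 0.1 there were 198. This count rests on the processing: 43 probes passed without background subtraction and 44 in the authors' values. Median centring gave 513, of which 11 were higher and 502 lower. With the replicate number as a random block 32 passed, 7 higher and 25 lower. This kind of fit had 6.16% false calls in data simulated with a correlation of 0.25 within a number. That share gives no error rate for the 32, as the simulated data held 200 changed probes. Their estimated consensus correlation averaged 0.185, against 0.0782 in the real data. Without replicate number 2 in every group 87 passed, 38 higher and 49 lower. The fixed replicate block gave 381.

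Delayed postconditioning gave 12 probes past the threshold, of which 11 were lower and 1 was higher than in IR, each with the same sign in all 3 replicates. Their median absolute log2 change was 0.52, the largest fall was -1.23 and the single rise was 0.45. All 12 were detected on most of the Post30 arrays. Without Post30 replicate 3 the count was 0, with the planned offset of 50 it was 2, and with plain subtraction it was 0. Without background subtraction 32 passed, 9 higher and 23 lower, and in the authors' values 28 passed, 8 higher and 20 lower. Median centring gave 179, of which 6 were higher and 173 lower. Without replicate number 2 in every group 21 passed, 6 higher and 15 lower. The fixed replicate block gave 104.

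The protocols were then compared with each other. Between postconditioning and preconditioning 0 probes passed with limma and 1348, or 8.19%, had an unadjusted p under 0.05. Between delayed postconditioning and preconditioning 0 passed and 768, or 4.67%, had an unadjusted p under 0.05, against 765, or 4.65%, between delayed postconditioning and postconditioning. In this fit, which does not pair the replicate numbers, both shares lie below the 5% that chance gives on average. With the fixed replicate block they were 7.10% and 6.63%, and with the random block 5.79% and 5.53%, all above 5%. Between delayed postconditioning and postconditioning 1 probe passed, lower after the delayed protocol by a log2 change of -0.67 (SE 0.085, adjusted p = 0.0241 with limma). It lay at -0.51 over IR after the delayed protocol and at 0.15 after postconditioning, and it did not pass when any 1 of the 6 extract pairs was left out. The median 95% interval of a difference between protocols reached 0.19 to either side on the log2 scale. It covers all probes at the scaled offset, detected or not, while on average 37.8% of mouse spots were detected in the group's channel. It therefore does not bound the differences of dim probes. The fixed block, in which the shared deviation cancels here, gave 0 probes for postconditioning against preconditioning, 2 for delayed postconditioning against preconditioning and 3 for it against postconditioning.

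The mean of the conditioning groups was tested against IR. A change in 1 protocol alone can pass this test, so a call is not by itself a change that the protocols share. With limma 160 of 16456 probes passed, 46 higher and 114 lower. Changes were small, with a median absolute log2 change of 0.20, and 1 probe reached 1.5-fold. Only 70 of the 160 had the same sign in all 9 extract pairs. Of the 12 probes that passed for delayed postconditioning alone, 7 were among the 160. In the group's channel 138 of the 160 were detected on most of the conditioning arrays. Same-numbered samples deviated together, and the share of false calls depends on how strongly. It was 24.5% in data simulated with a correlation of 0.25 within a number, 9.04% with 0.0782 and 5.79% with 0. Those data held 200 changed probes, with log2 changes of 0.25, 0.5 or 1, so the shares do not give an error rate for the 160. The consensus correlation estimated from the real data was 0.0782, and the same estimate from the simulated data was 0.185, 0.0314 and -0.0379. With the replicate number as a random block, 43 probes passed, 10 higher and 33 lower, all among the 160. With the planned offset of 50 the count was 0, with a fixed block 654, and without background subtraction 1184. Without background subtraction 503 were higher and 681 lower, and in the authors' values 1136 passed, 482 higher and 654 lower. Median centring gave 3619, of which 688 were higher and 2931 lower. Without replicate number 2 in every group 117 passed, 63 higher and 54 lower, and 41 of them were among the 160. Leaving out 1 extract pair gave 28 to 132 probes, with 28 to 46 in 7 of the 9 cases, and plain subtraction left 1.

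Among the 160 probes that passed, Mm::M200013771 fell most against IR over the conditioning groups, by a log2 change of -0.63 (SE 0.074, adjusted p = 0.00504 with limma). Its mean ratios were -0.24 ± 0.33 in PreC, -0.55 ± 0.27 in PostC and -1.09 ± 0.13 in Post30 (SD, n = 3). It was -0.35 ± 0.35 in the non-ischemic region. The probe Mm::M200000579 fell by 0.58 (SE 0.13, adjusted p = 0.0463 with limma) and lay at -1.26 ± 0.70 in the non-ischemic region (SD, n = 3). With the replicate number as a random block its adjusted p was 0.0686, and it did not pass when any 1 of the 9 extract pairs was left out (adjusted p from 0.0576 to 0.121). The probe Mm::M200000541 rose by 0.32 (SE 0.042, adjusted p = 0.0104 with limma) and Mm::M200008836 by 0.27 (SE 0.045, adjusted p = 0.0176 with limma). In the non-ischemic region, without conditioning, these 2 probes lay at similar ratios over IR, 0.31 ± 0.11 and 0.23 ± 0.24 (SD, n = 3). Neither passed under median centring, with log2 changes of 0.16 and 0.10 and adjusted p of 0.0959 and 0.305 with limma. Without any 1 of PreC, PostC and Post30 replicate 2, Mm::M200008836 did not pass (adjusted p from 0.0537 to 0.0593 with limma). Scaled to the control probes 1DR to 6DR, both had the opposite sign, at -0.13 and -0.17, by construction: that scaling moves all probes alike and puts their median at -0.44. With plain subtraction 0 of the 4 probes passed, at log2 changes of 0.44 for Mm::M200000541, 0.38 for Mm::M200008836, -0.64 for Mm::M200013771 and -0.56 for Mm::M200000579. With the offset of 50 none passed either, and the changes, in the same order, shrank to 0.05, 0.04, -0.27 and -0.17. Each of the 4 probes was detected on 18 of 18 conditioning arrays in the group's channel.

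**Figure D1:**
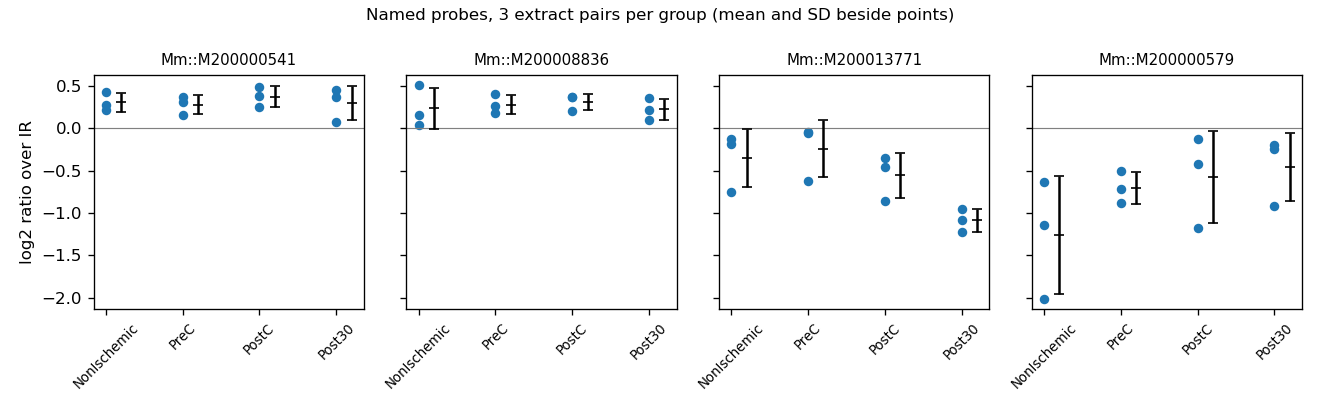
Log2 ratio over IR RNA (vertical axis) of the 4 named probes in each group (horizontal axis). Points are the 3 extract pairs, and the bar beside them is the mean with SD. For Mm::M200013771 the mean was -1.09 in Post30 and -0.24 in PreC.

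The conditioning profiles were set against that of the non-ischemic region to ask whether conditioned tissue resembled it. Across 16309 probes, which are not independent replicates, ratios over IR correlated with those of the non-ischemic region with r = 0.302 for PreC, 0.357 for PostC and 0.346 for Post30. Simulated unchanged groups with IR deviations shared within a replicate number gave 0.251, 0.244 and 0.248. A single shared IR pool gave 0.501, 0.504 and 0.507. The simulation by number gave every pair of groups the same correlation of 0.245. Same-numbered pairs with NonIschemic correlated with r from 0.0102 to 0.378, so its values may be too high for these comparisons. The covariance was 0.00333 for PreC, 0.00439 for PostC and 0.00364 for Post30, against simulated values of 0.00134, 0.0013 and 0.00132 with IR deviations shared by number and 0.00537, 0.0054 and 0.00545 with a single pool. All 3 observed covariances lie below those of a single pool. Its simulated deviation had an assumed size, as one shared by all arrays cannot be estimated from them, so this comparison decides nothing. Shared IR RNA alone is therefore not excluded. Under median centring r was 0.503, 0.529 and 0.534. Without replicate 2, r was 0.251 for PreC, 0.012 for PostC and 0.123 for Post30.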

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

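The tests of loess and of the amount of control RNA were chosen after the result was seen. The control probes 1DR to 6DR, which no comparison uses, stood higher relative to mouse probes after loess in PostC and Post30 than in the other groups. Their mean log2 ratio over IR was 0.75 ± 0.05 in PostC and 0.62 ± 0.10 in Post30, against -0.04 ± 0.18 in PreC and 0.07 ± 0.38 in NonIschemic (SD, n = 3). An exact two-sided permutation test of PostC against PreC gave p = 0.1, the smallest that 3 against 3 allows, and 0.15 after adjustment over all pairs of groups. Loess is argued against as the whole cause, since the difference between PostC and PreC was 0.83 (SE 0.12) under median centring. Under that setting Post30 did not stand apart from NonIschemic, at 0.37 ± 0.38 against 0.04 ± 0.55 (SD, n = 3). Dye is argued against too, since the smaller of the differences in the 2 dye orientations was 0.69 (SE 0.15). The ratio controls 1RC to 4RC shifted by 0.59 (SE 0.093) between the same groups. An unequal amount of added control RNA and a lower share of mouse mRNA both predict such a shift and cannot be told apart. The files do not say what these controls are or when they were added.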

How the results depend on the processing

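The scaled offset behind the reported values, the random block, the scaling to control probes and the fits without replicate number 2 were chosen after seeing the data, while the offset of 50 was planned. The cause of a change was not tested unless given. Counts below follow 1 order of comparisons: ischemic against non-ischemic region, preconditioning, postconditioning and delayed postconditioning against IR, postconditioning against preconditioning, delayed postconditioning against postconditioning and against preconditioning, and any conditioning against IR. As reported they were 0, 0, 0, 12, 0, 1, 0 and 160. They were 0, 0, 43, 32, 1, 2, 0 and 1184 without background subtraction, and 0, 0, 44, 28, 1, 2, 0 and 1136 in the authors' values. Of the 160 probes, 150 passed in each of these. Plain subtraction with a floor of 1 gave 1, 0, 0, 0, 0, 0, 0 and 1. Median centring gave 40, 1, 513, 179, 0, 0, 0 and 3619. With an offset of 50 the counts were 0, 0, 0, 2, 0, 0, 0 and 0, so every call of any conditioning was lost under the offset first planned.

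Taking the 24 arrays as replicates with a dye effect gave 822, 55, 941, 193, 109, 17, 18 and 1192, in a fit that counts each extract pair as 2 samples. With the pair as a random block they were 519, 32, 635, 140, 20, 10, 15 and 820. The fixed replicate block gave 386, 40, 381, 104, 0, 3, 2 and 654, and it changed each call except postconditioning against preconditioning. The replicate number as a random block gave 0, 0, 32, 14, 0, 2, 0 and 43. Own replicates alone gave 0, 12, 2, 10, 0, 0, 0 and 201. Array weights gave 252 for any conditioning and left the other counts as they were. An adjusted p under 0.1 gave 31, 0, 198, 20, 0, 2, 0 and 501, and the 1.5-fold threshold gave 0, 0, 0, 4, 0, 1, 0 and 1. Probes above median intensity and marked spots kept moved no count by over 1.5 times, and Aquantile leaves ratios as they are by construction.

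Scaled to the control probes 1DR to 6DR the counts were 72, 37, 16446, 16410, 16387, 1, 16186 and 16431. This moved the median log2 ratio of all probes to -0.75 for postconditioning and -0.62 for delayed postconditioning against IR, 1 factor per extract pair that all probes share. Mm::M200000541 and Mm::M200008836 then had values of -0.13 and -0.17. Under plain subtraction the adjusted p was 0.19 for Mm::M200000541, 0.286 for Mm::M200008836, 0.19 for Mm::M200013771 and 0.431 for Mm::M200000579. Mm::M200008836 did not pass without PreC, PostC or Post30 replicate 2 (adjusted p from 0.0537 to 0.0593), and Mm::M200000579 did not with marked spots kept (0.0502).

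Leaving out 1 extract pair gave 0 to 1 probes for the region, 0 to 2 for preconditioning, 0 to 2 for postconditioning, 0 to 10 for delayed postconditioning, 0 to 1 for postconditioning against preconditioning, 0 to 0 for delayed postconditioning against postconditioning, 0 to 1 for it against preconditioning and 28 to 132 for any conditioning. The 0 for delayed postconditioning came without Post30 replicate 3. Any conditioning fell to 32, 28, 33 and 32 without PreC replicates 1 and 2 and PostC replicates 2 and 3. It fell to 84 without PostC replicate 1, and to 46, 38 and 45 without Post30 replicates 1, 2 and 3. Without replicate number 2 in every group, which leaves out 1 extract pair of each of the 4 groups, the counts were 0, 4, 87, 21, 0, 0, 5 and 117.

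The correlation with the non-ischemic region became 0.503 for PreC, 0.529 for PostC and 0.534 for Post30 under median centring. Leaving out a replicate number gave 0.213 to 0.369 for PreC, 0.012 to 0.448 for PostC and 0.123 to 0.399 for Post30, the lowest of the last pair without number 2. With conditioning from number 1 and the region from the others it was 0.0027 for PreC, 0.113 for PostC and 0.0337 for Post30. From number 2 it was 0.242, 0.304 and 0.239 for PreC, PostC and Post30. From number 3 it was 0.194, 0.102 and 0.0721 for PreC, PostC and Post30. Slide and scan batches are not in the files and were not run, and the gene list alternatives were not run without gene names. At most 49.8% of mouse spots were above empty spots in any channel, which limits what dim probes can show.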

Other observations

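The tests of covariance were chosen after the result was seen. Of the 160 probes that differed between any conditioning and IR, 147 had the same direction in the non-ischemic region over IR, with a median log2 ratio of 0.16 in that direction. The same IR RNA is in both ratios, so this share lies above chance with no effect at all. A candidate explanation is a deviation of the IR RNA that is the same on all arrays, which predicts equal covariances between all groups. Across different replicate numbers the covariance of PostC with Post30 exceeded that of PreC with Post30 by 0.00176 (jackknife SE 0.00129), which does not separate them. That of NonIschemic was 0.00227 with PreC, 0.00325 with PostC and 0.00198 with Post30. With 1 number left out these ranged from -0.000271 to 0.00595, and their equality with the other covariances was not tested. A deviation of the IR RNA shared only within a replicate number predicts a covariance of 0 between conditioning groups across different numbers. For PostC with Post30 it was 0.00191 (jackknife SE 0.000535), above 0 in 6 of 6 pairings of different numbers, which argues against that deviation as the whole cause for this pair, although the SE rests on 3 numbers and this is the highest of 3 pairs. It stays open for PreC with PostC, at 0.000926 (SE 0.00179), for PreC with Post30, at 0.000145 (SE 0.00107), and for the mean of the 3 pairs, at 0.000993 (SE 0.000946). A shared change of the protocols and a deviation of the IR RNA that is the same on all arrays cannot be told apart here, as every array carries IR RNA. PostC and Post30 also shared higher control probes 1DR to 6DR, at 0.75 and 0.62 over IR against -0.04 in PreC. Whether what raised these controls also adds to the covariance of PostC with Post30 was not tested.

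Turned signs and other splits were counted for each comparison. For the ratios against IR, the signs of 1 replicate number were turned at a time, which makes 4 patterns and is too few for a share under 0.05. Delayed postconditioning gave 12 probes against a highest other of 0 (1 of 4 patterns as large), and any conditioning gave 160 against 20 (1 of 4). A count of 0 is reached by every pattern or split by definition, so nothing was tested for the ischemic against the non-ischemic region, preconditioning and postconditioning (4 of 4 patterns, highest others 0, 0 and 2). Between protocols the 10 splits of 6 pairs are too few as well. The same definition holds for postconditioning against preconditioning, with a highest other of 0, and for delayed postconditioning against preconditioning, with 20 (10 of 10 each). Delayed postconditioning against postconditioning gave 1 probe against a highest other of 8 (2 of 10). The 8 and the 20 came from the 6 splits that put same-numbered samples together and so hold differences between numbers. Among the 4 splits that part every pair, as the real one does, the highest other was 0 in each of these comparisons. With signs turned for single extract pairs, 1 of 100 patterns of any conditioning reached 160, the real one, and the highest other was 58. That share excludes chance only if pairs of one replicate number vary independently, which their correlations of 0.215 to 0.396 between conditioning groups contradict.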
